A study of Mus musculus with 8 samples.

How the data were processed

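The authors deposited FPKM for 12193 gene loci on mm10 for each of the 8 libraries, and these values were analysed as deposited. Per the labels, RNA came from column extraction, and cDNA was made with Superscript III for Illumina sequencing; strandedness is not given in the sources used here. The submitters' processing notes name Trimmomatic 0.22, TopHat2 2.0.8, HTSeq 0.5.4 and DESeq with no version, and the program that computed FPKM and the rule that chose the loci are not given in the sources used here. FPKM divides each gene by its length and by the library total, so a change in a few abundant transcripts moves all others.

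Depth is not given in the sources used here and was estimated from the smallest steps of FPKM in 73 genes with a single transcript, which gave 49.5 to 57.9 M fragments per library (Neo 1 quartiles 47.5 to 59.1). Of the ratios of low genes, 28.6 to 33.3% lay at ratios of whole reads, against 9.70 to 10.9% at random. FPKM sums ran from 683834 to 808072 and medians from 14.3 to 14.7. The 648 small RNA genes are short, and their FPKM rests on few reads or on fragments that size selection removes. Rn7sk was 60705 FPKM in Neo 1 and 0 in the other 7 libraries. Start plus 1 and end matched the GENCODE M21 gene for 9829 of 12129 loci with an M21 identifier, so starts were read as 0-based.

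The groups were Neo water, EGFR water, EGFR with EGF for 3 h and EGFR with EGF for 18 h, 2 libraries each. The groups, comparisons, tests, gene lists, named-gene rule and all alternatives but the restriction to protein-coding genes were fixed before the data were examined. Genes at FPKM of at least 1 in at least 2 libraries (10874) were tested by limma-trend on log2(FPKM + 1) with all 4 groups in the fit (4 residual and 3.29 prior degrees of freedom), with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Time classes and overlaps used these calls, and 100 simulations of unchanged groups gave the values for shared controls. The analysis was tested on simulations with 200 of 10874 genes raised or lowered by known folds. It recovered 97.0 to 99.7% of genes changed 1.5-fold and 98.2 to 99.4% changed 2-fold, and 3.32 to 4.47% of calls were wrong. These rates need not hold at low FPKM or in real comparisons, with 653 to 3663 calls.

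The 22 gene lists were corticotrope identity and POMC pathway, immediate early genes, ERK pathway, STAT3 targets, STAT5 and SOCS family, ERBB, cAMP and calcium response, glucocorticoid response, S phase, G2/M, CDK inhibitors and p53 targets, cholesterol synthesis, glycolysis and hypoxia, ribosome biogenesis, unfolded protein and integrated stress response, interferon response, NF-kB, adhesion and proteases, PI3K-FOXO targets, neuroendocrine secretion, other pituitary lineages, and fibroblast, endothelial and blood cells. Only 9 of 28 interferon and 9 of 44 adhesion genes listed had values. Lists with at least 5 tested members were tested by limma camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Named genes were Egfr, Pomc, Stat3, Tbx19, Nr4a1, Socs3, Egr1 and Fos in each comparison, the 8 largest called increases and decreases (5 between 18 h and 3 h) with non-overlapping libraries and mean FPKM of at least 5, without clone, pseudogene, small nucleolar and ribosomal RNA names, and up to 4 called members of each list described. Where fewer than 2 members were called, the 2 with the highest expression were named instead. Some genes that this rule picks are not reported here and count at most in totals. Transcripts of genes named or listed, or called in opposite directions at 3 h and 18 h, were aligned with minimap2 2.31 to all M21 transcripts, and a copy was at least 95% identical over at least 200 bases.

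Alternatives were pseudocount 0.1, no filter or FPKM of at least 5, median-ratio, common-sum and quantile scaling, only the 2 groups of a comparison in the fit, no variance trend, the replicate number as a block, each library left out, stricter thresholds, camera with an estimated correlation and fry, and, added after seeing the data, protein-coding genes only. Count models were left out because counts are not used here, and no test of sex, batch or outliers was made. Analyses ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.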

Results

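The series asks how EGF acts on transcription in AtT-20 cells, a mouse corticotrope tumour line that makes Pomc, the precursor of ACTH, and its title names STAT3. A control line carrying Neo and a line carrying EGFR received water, labelled 3 h, and the EGFR line received EGF for 3 h or for 18 h, with n = 2 libraries in each of the 4 groups. The libraries are called Neo 1 and 2, water 1 and 2, 3 h EGF 1 and 2 and 18 h EGF 1 and 2 below, after their replicate numbers. The groups allow EGFR to be compared with Neo in water, each EGF time with water in the EGFR line, and 18 h with 3 h of EGF. No Neo library received EGF, so whether the response to EGF needs the introduced receptor cannot be tested. No water library is labelled 18 h, so time in culture cannot be separated from EGF at 18 h. Levels are mean FPKM ± SD over n = 2 libraries, the tested group first, and fold changes are on the log2(FPKM + 1) scale, which understates genes of low FPKM. Brackets after a gene give its log2 fold change, its levels in the 2 groups and its limma adjusted p, in that order. All p-values measure only the spread between these samples, which may be technical, since the labels do not say that replicates are separate cultures.

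Egfr (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158, plus strand), the receptor of EGF, and Pomc (ENSMUSG00000020660, chromosome 12, 3954951 to 3960618, plus strand) are protein-coding genes of the mm10 assembly in 1-based coordinates, as are Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540, minus strand), Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047, minus strand), Tbx19 (ENSMUSG00000026572, chromosome 1, 165137855 to 165160773, minus strand) and all other genes named below, except Rnu5g, which is a small nuclear RNA gene. Each value covers a gene locus, so transcripts of a gene are not separated. Values of Acat3, Bnip3, Dusp5, Etv5, Fdft1, Hbp1, Idi1, Isg15, Nab2, Oas1a, Selenbp1 and Shc1, which share at least 20% of their transcript with other genes, and of Fdps, Kif20a and Tsr1, with at least 20% of exon bases in others, are uncertain in source. Shorter shared stretches occur in Ccna2, Ccne2, Cdkn1a, Ddx21, Fbxl20, Hmgcs1, Hsp90b1, Il6ra, Nek2, Neurod1, Rrm2, Slbp, Stc1, Txnip and Unc13a. The labels do not give the species of the introduced EGFR, and the Egfr value is that of the mouse locus. Nr4a1, Egr1 and Fos, which were to be named in every comparison, are not analysed here because their loci have no values in the tables used.

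Replicates correlated at r = 0.987 to 0.991 across genes, at an estimated depth of 49.5 to 57.9 M fragments. Without small RNA genes, the first principal component (47.7% of the variance) set the 4 water libraries (−10.89 to −8.58) apart from the 4 EGF libraries (5.81 to 13.46), and the next one (24.1%) set 3 h of EGF (−12.14 and −10.34) apart from 18 h (8.74 and 7.13). Small RNA genes held 39.0% and 33.2% of summed FPKM in Neo 1 and 2, and 29.1 to 32.8% in the 6 EGFR libraries. Fibroblast, endothelial and blood cell markers had 0 genes with values to test.

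**Figure D1:**
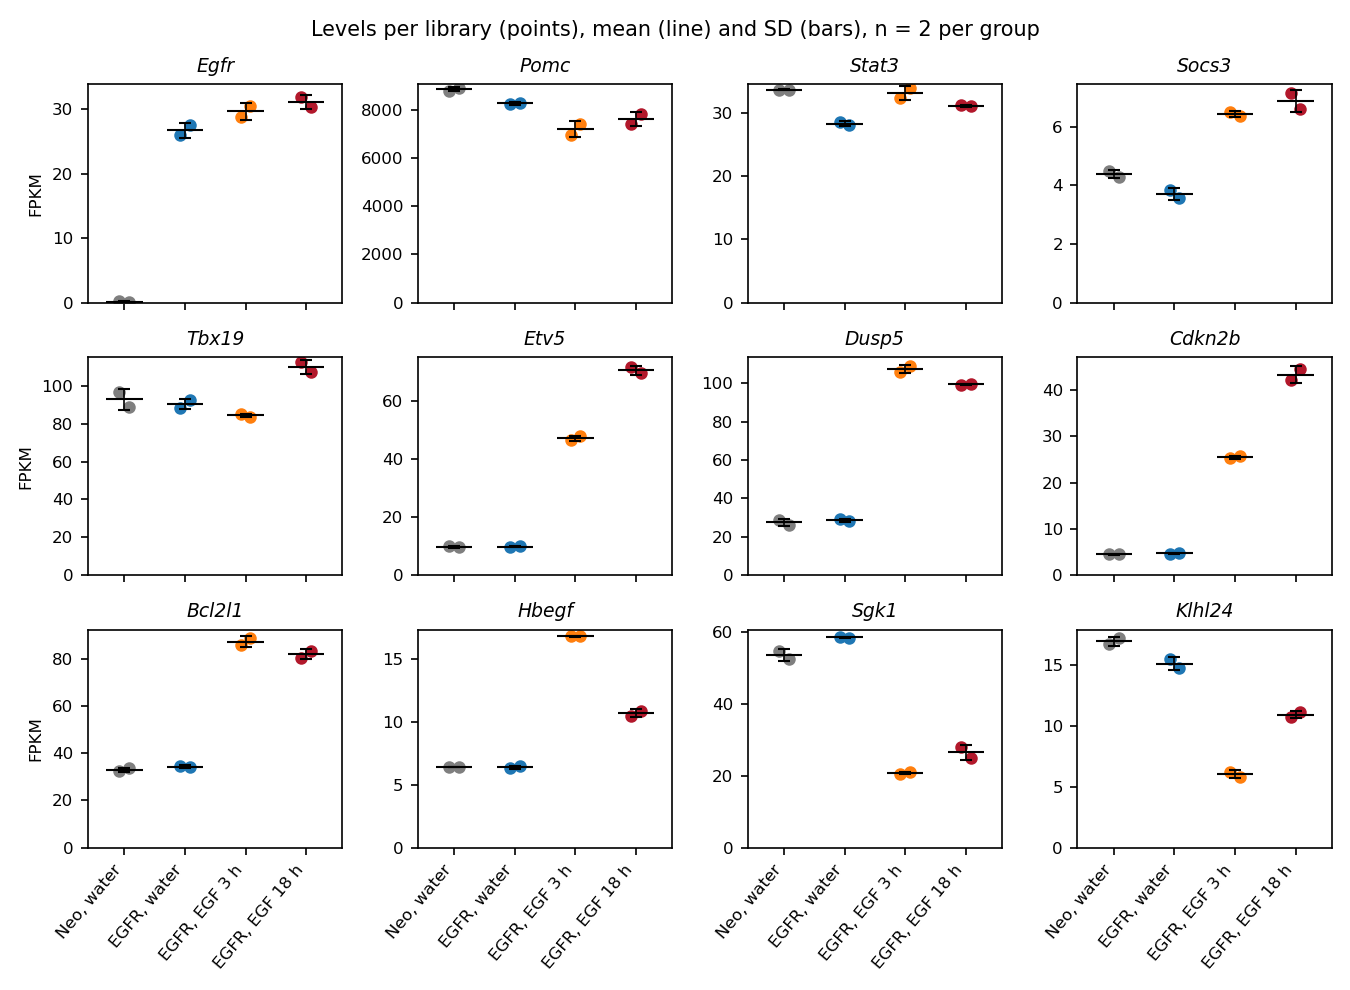
FPKM of 12 genes in each of the 8 libraries (points), with the group mean (line) and SD (bars) for Neo water, EGFR water, EGF 3 h and EGF 18 h, n = 2 each. Egfr is near 0 in Neo and 26.7 in EGFR water, while Pomc is 8274 in EGFR water and 7206 after 3 h of EGF.

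The EGFR line was compared with the Neo line in water to ask what the introduced receptor line changes without added ligand. The labels do not say whether a line is a single clone or a pool, so a difference between the lines need not come from the receptor. Egfr itself was the largest difference named (4.60, 26.7 ± 1.13 against 0.147 ± 0.114, 2.86e-07), and several of the next largest increases named were enzymes of cholesterol synthesis. Of the 4 genes called at least 2-fold higher only Egfr is named, so larger increases than those of the enzymes exist. Higher genes were Hsd17b7, an enzyme of cholesterol synthesis, (0.57, 17.1 ± 0.9752 against 11.2 ± 0.897, 0.00474), Mvk, mevalonate kinase, (0.53, 30.9 ± 0.535 against 21.2 ± 1.40, 0.00673) and Fdps, farnesyl diphosphate synthase, (0.52, 354 ± 1.02 against 247 ± 1.09, 8.63e-04). So were Pmvk, phosphomevalonate kinase, (0.49, 96.1 ± 1.05 against 68.3 ± 1.11, 5.21e-04) and Lss, lanosterol synthase, (0.49, 71.1 ± 1.58 against 50.5 ± 2.28, 0.0123). They were joined by Acat3, an acetyl-CoA acetyltransferase, (0.50, 11.1 ± 0.774 against 7.54 ± 0.208, 0.00950) and Foxn3, a forkhead transcription factor, (0.52, 19.6 ± 1.69 against 13.4 ± 2.05, 0.0393). Large decreases were Mgarp, a mitochondrial protein, (−1.82, 1.08 ± 0.229 against 6.30 ± 0.0963, 2.51e-04), Upk3a, a uroplakin, (−1.63, 2.42 ± 0.0310 against 9.63 ± 1.43, 5.21e-04), Bnip3, a hypoxia-induced mitophagy receptor, (−1.60, 64.2 ± 5.37 against 196 ± 6.58, 1.78e-04) and Ndrg1, a hypoxia-induced gene, (−1.44, 9.83 ± 0.486 against 28.4 ± 2.10, 3.30e-04). Next were Slc16a3, a lactate exporter, (−1.31, 39.6 ± 1.86 against 99.6 ± 1.92, 1.61e-04) and Selenbp1, a selenium-binding protein, (−1.27, 2.66 ± 0.107 against 7.86 ± 0.778, 6.94e-04). After these came Bhlhe40, a transcriptional repressor of the clock and hypoxia pathways, (−1.14, 2.53 ± 0.545 against 6.74 ± 0.402, 0.00203) and Rnu5g, a spliceosomal RNA, (−1.14, 218 ± 25.04 against 482 ± 46.6, 9.62e-04). Stat3 was lower (−0.24, 28.3 ± 0.368 against 33.7 ± 0.0359, 0.0112). Pomc (−0.10, 8274 ± 47.4 against 8864 ± 92.9, 0.382), Socs3 (−0.19, 3.70 ± 0.204 against 4.38 ± 0.144, 0.0872) and Tbx19 (−0.04, 90.4 ± 2.82 against 92.8 ± 5.49, 0.670) did not pass. Mvk lost its call without water 1 (adjusted p = 0.0647). Lss did not keep its call without Neo 1, Neo 2, water 1 or water 2 (adjusted p = 0.0513 to 0.0912). Acat3 had no call without Neo 1 or water 1 (adjusted p = 0.0650 and 0.0700). Foxn3 lost its call without the FPKM filter, with only the 2 groups fitted, without the variance trend or without Neo 2, water 1, water 2, 18 h EGF 1 or 18 h EGF 2 (adjusted p = 0.0505 to 0.186). Stat3 did not keep its call after rescaling to a common sum or without Neo 1, water 1 or water 2 (adjusted p = 0.0650 to 0.126).

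Of 10874 genes tested by limma-trend, 338 were higher and 315 lower at adjusted p below 0.05, of which 4 and 18 changed at least 2-fold. Higher genes were 51.8% of the calls, against 43.8% after median-ratio rescaling (343 higher and 441 lower) and 75.4% after rescaling to a common sum (315 higher and 103 lower). Higher and lower counts became 108 and 129 with only the 2 groups fitted, 38 and 85 without Neo 1, 77 and 172 without Neo 2, 22 and 63 without water 1, 26 and 87 without water 2, 155 and 203 without 18 h EGF 1, 144 and 197 without 18 h EGF 2 and 530 and 444 with protein-coding genes only. Across the 19 lists with at least 5 genes tested, camera called 4 up and 7 down, fry 4 and 7, and camera with an estimated correlation 0 and 0, where 6 lists had an unadjusted p under 0.05. The Neo libraries also held the larger share of small RNA (39.0% and 33.2% of summed FPKM, against 30.9% and 31.9% in EGFR water).

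Glycolysis and hypoxia-induced genes were lower in the EGFR line almost without exception. Of the 24 glycolysis and hypoxia genes tested, 0 were higher, 22 were lower and 2 did not pass (0 were higher and 24 were lower adjusted over the list alone, median log2 fold change −0.65). The glycolysis and hypoxia list was called down by camera at adjusted p = 5.61e-35 (adjusted p = 0.114 with an estimated correlation). Beside Bnip3, Ndrg1 and Slc16a3, Pfkl, a phosphofructokinase of glycolysis, (−1.12, 21.4 ± 1.72 against 47.6 ± 2.80, 3.30e-04) was lower. Cholesterol synthesis genes were higher. Among 23 cholesterol genes tested, 18 were higher, 0 were lower and 5 did not pass (21 were higher and 0 were lower adjusted over the list alone, median log2 fold change 0.34). The cholesterol list was called up by camera at adjusted p = 6.09e-18 (adjusted p = 0.114 with an estimated correlation). The cholesterol counts of higher and lower members became 10 and 0 without Neo 1, 7 and 0 without water 1 and 8 and 0 without water 2.

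**Figure D2:**
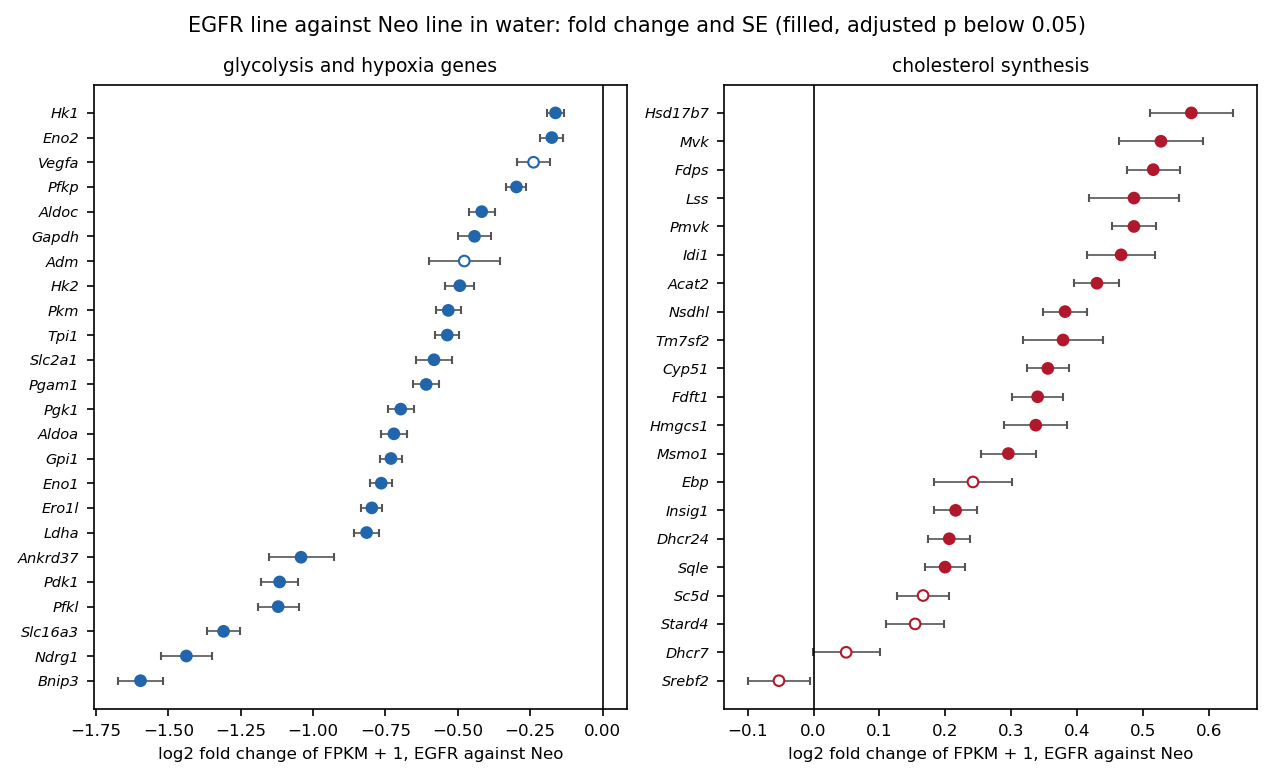
Log2 fold change ± SE, EGFR line against Neo line in water, of genes of the glycolysis and hypoxia list and of the cholesterol synthesis list (filled points, adjusted p below 0.05), n = 2 per group. 22 of 24 glycolysis and hypoxia genes shown lie below 0 with a call and 16 of 21 cholesterol genes shown lie above 0 with a call.

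Genes of mitosis that differed were higher in the EGFR line. Of the 29 G2/M genes tested, 16 were higher, 0 were lower and 13 did not pass (25 were higher and 0 were lower adjusted over the list alone, median log2 fold change 0.19). The G2/M list was called up by camera at adjusted p = 2.74e-15 (adjusted p = 0.114 with an estimated correlation). They include Cenpf, a kinetochore protein, (0.35, 18.5 ± 0.414 against 14.3 ± 0.608, 0.00669), Nek2, a centrosomal kinase, (0.30, 40.0 ± 0.538 against 32.4 ± 0.339, 0.00980), Cdc20, an activator of the anaphase-promoting complex, (0.26, 71.0 ± 0.462 against 59.2 ± 1.47, 0.0264) and Cdca8, the chromosomal passenger borealin, (0.25, 60.8 ± 1.12 against 50.8 ± 0.0134, 0.0211). The G2/M counts became 0 to 10 higher and 0 lower without Neo 1, Neo 2, water 1, water 2, 18 h EGF 1 or 18 h EGF 2. Cenpf lost its call without water 2 (adjusted p = 0.0589). Nek2 did not keep its call without Neo 1, water 1 or water 2 (adjusted p = 0.0625 to 0.0874). Cdc20 had no call without Neo 1, Neo 2, water 1, water 2, 18 h EGF 1 or 18 h EGF 2 (adjusted p = 0.0501 to 0.148). Cdca8 lost its call without Neo 1, Neo 2, water 1 or water 2 (adjusted p = 0.0761 to 0.142).

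Targets of FOXO factors, which PI3K signalling restrains, were lower where they differed. Among 17 PI3K-FOXO genes tested, 0 were higher, 4 were lower and 13 did not pass (0 were higher and 5 were lower adjusted over the list alone, median log2 fold change −0.13). The PI3K-FOXO list was called down by camera at adjusted p = 2.60e-04 (adjusted p = 0.114 with an estimated correlation). Lower members were Txnip, a thioredoxin inhibitor, (−0.65, 36.8 ± 0.767 against 58.2 ± 4.45, 0.00206), Cited2, a transcriptional coregulator, (−0.39, 5.43 ± 0.0252 against 7.42 ± 0.0507, 0.00656), Tob1, an antiproliferative factor, (−0.36, 11.5 ± 0.316 against 15.04 ± 0.408, 0.01003) and Fbxo32, the ubiquitin ligase atrogin-1, (−0.26, 4.88 ± 0.145 against 6.03 ± 0.224, 0.0461). The PI3K-FOXO counts of higher and lower members became 0 and 2 without Neo 1, 0 and 1 without water 1 and 0 and 2 without water 2. Cited2 lost its call without water 1 (adjusted p = 0.0614). Tob1 did not keep its call without Neo 1, water 1 or water 2 (adjusted p = 0.0520 to 0.0862). Fbxo32 had no call with pseudocount 0.1, with an FPKM filter of 5, after rescaling to a common sum, with only the 2 groups fitted or without Neo 1, Neo 2, water 1, water 2, 3 h EGF 1, 3 h EGF 2, 18 h EGF 1 or 18 h EGF 2 (adjusted p = 0.0551 to 0.218).

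Corticotrope genes that differed between the lines were lower in the EGFR line. Of the 21 corticotrope genes tested, 0 were higher, 3 were lower and 18 did not pass (0 were higher and 3 were lower adjusted over the list alone, median log2 fold change −0.08). The corticotrope list was called down by camera at adjusted p = 6.22e-04 (adjusted p = 0.135 with an estimated correlation). The lower members were Neurod1, a corticotrope transcription factor, (−0.24, 11.1 ± 0.347 against 13.2 ± 0.385, 0.0256), Pcsk1n, an inhibitor of prohormone convertase, (−0.20, 23.2 ± 0.117 against 26.8 ± 1.29, 0.0322) and Sstr5, a somatostatin receptor, (−0.19, 14.4 ± 0.114 against 16.6 ± 0.0363, 0.0243). The corticotrope counts became 0 higher and 0 to 1 lower after rescaling to a common sum or without Neo 1, Neo 2, water 1, water 2, 18 h EGF 1 or 18 h EGF 2. Neurod1 lost its call after rescaling to a common sum, with only the 2 groups fitted or without Neo 1, Neo 2, water 1, water 2, 18 h EGF 1 or 18 h EGF 2 (adjusted p = 0.0511 to 0.161). Pcsk1n did not keep its call after rescaling to a common sum, with only the 2 groups fitted or without Neo 1, water 1, water 2, 18 h EGF 1 or 18 h EGF 2 (adjusted p = 0.0593 to 0.167). Sstr5 had no call after rescaling to a common sum, with only the 2 groups fitted or without Neo 1, Neo 2, water 1, water 2 or 18 h EGF 2 (adjusted p = 0.0503 to 0.235).

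EGF for 3 h was compared with water in the EGFR line to ask what the ligand changes early. The largest increases were Cdkn2b, the CDK inhibitor p15, (2.21, 25.4 ± 0.282 against 4.71 ± 0.0793, 2.67e-07), Gprc5c, an orphan G protein-coupled receptor, (2.18, 33.4 ± 2.64 against 6.59 ± 0.583, 8.63e-06), Hes1, a repressor downstream of Notch, (2.18, 15.5 ± 0.974 against 2.66 ± 0.367, 2.08e-05) and Etv5, an ETS transcription factor induced through ERK, (2.15, 47.3 ± 0.824 against 9.86 ± 0.195, 2.67e-07). These were followed by Stc1, a secreted glycoprotein, (2.05, 18.1 ± 1.44 against 3.60 ± 0.227, 5.26e-06), Enc1, an actin-binding kelch protein, (1.89, 58.0 ± 0.635 against 14.96 ± 0.367, 2.67e-07), Dusp5, a nuclear phosphatase of ERK, (1.88, 107 ± 2.10 against 28.5 ± 0.721, 1.52e-06) and Sh2d5, an SH2-domain adapter, (1.67, 8.26 ± 0.4997 against 1.91 ± 0.0242, 4.17e-05). Cdkn2b (ENSMUSG00000073802, chromosome 4, 89306289 to 89311032, minus strand) and Etv5 (ENSMUSG00000013089, chromosome 16, 22381309 to 22439719, minus strand) are also among the largest at 18 h. Large decreases were Sgk1, a kinase induced by glucocorticoids, (−1.45, 20.7 ± 0.368 against 58.4 ± 0.222, 1.02e-05), Klhl24, a kelch-like ubiquitin ligase adapter, (−1.20, 6.02 ± 0.308 against 15.1 ± 0.525, 1.31e-05), Amotl2, an angiomotin-like junction protein, (−1.17, 4.48 ± 0.0177 against 11.3 ± 0.332, 5.28e-05) and Mycl, a MYC family transcription factor, (−1.01, 4.20 ± 0.192 against 9.49 ± 0.248, 5.28e-05). Smaller decreases were Hbp1, a transcriptional repressor of growth genes, (−0.98, 13.1 ± 1.16 against 26.9 ± 0.607, 8.10e-05), Tat, tyrosine aminotransferase, (−0.92, 5.76 ± 0.325 against 11.8 ± 1.08, 0.00156), Foxn3 (−0.92, 9.87 ± 1.05 against 19.6 ± 1.69, 0.00146) and Fbxl20, an F-box protein, (−0.88, 4.77 ± 0.630 against 9.59 ± 0.101, 3.10e-04). Stat3 (0.22, 33.2 ± 1.05 against 28.3 ± 0.368, 0.00376) and Socs3, a feedback inhibitor induced through STAT3, (0.66, 6.41 ± 0.0993 against 3.70 ± 0.204, 4.22e-04) rose. Tbx19, the corticotrope factor TPIT, (−0.10, 84.4 ± 0.823 against 90.4 ± 2.82, 0.156) and Egfr (0.15, 29.7 ± 1.29 against 26.7 ± 1.13, 0.157) did not pass.

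Pomc, the gene in the series title, was not higher after 3 h of EGF (−0.20, 7206 ± 318 against 8274 ± 47.4, 0.0531). The 95% interval of its log2 fold change ran from −0.35 to −0.05, from −0.28 to −0.04 after median-ratio rescaling and from −0.30 to 0.06 after rescaling to a common sum. Pomc passed the test as lower with pseudocount 0.1 (adjusted p = 0.0415), without the variance trend (adjusted p = 0.0181), without 3 h EGF 2 (adjusted p = 0.0342) and with protein-coding genes only, a choice made after seeing the data (adjusted p = 0.0102).

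After 3 h, of 10874 genes tested by limma-trend, 1283 were higher and 2142 lower at adjusted p below 0.05, of which 44 and 10 changed at least 2-fold. Higher genes were 37.5% of the calls, against 53.1% after median-ratio rescaling (1772 higher and 1562 lower) and 75.4% after rescaling to a common sum (1349 higher and 441 lower). Higher and lower counts became 680 and 808 without water 1, 616 and 829 without water 2 and 769 and 947 without 3 h EGF 1. Across the 19 lists with at least 5 genes tested, camera called 8 up and 1 down, fry 9 and 4, and camera with an estimated correlation 0 and 0, where 3 lists had an unadjusted p under 0.05.

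Feedback and output genes of the ERK pathway, which EGFR activates, were among the strongest responses. Among 12 ERK genes tested, 8 rose, 2 fell and 2 did not pass (8 rose and 2 fell adjusted over the list alone, median log2 fold change 0.60). The ERK list was called up by camera at adjusted p = 2.72e-05 (adjusted p = 0.227 with an estimated correlation). With Etv5 and Dusp5, Plaur, the urokinase receptor, (1.39, 4.99 ± 0.343 against 1.298 ± 0.228, 1.08e-04) and Spred1, an inhibitor of RAS-ERK signalling, (0.997, 5.03 ± 0.445 against 2.02 ± 0.0313, 1.91e-04) rose. The ERK counts became 8 rising and 1 falling after median-ratio rescaling, after rescaling to a common sum or without water 1, water 2, 3 h EGF 1 or 3 h EGF 2. Of the 18 STAT3 target genes tested, 8 rose, 4 fell and 6 did not pass (8 rose and 4 fell adjusted over the list alone, median log2 fold change 0.11). The STAT3 target list was called up by camera at adjusted p = 0.00172 (adjusted p = 0.245 with an estimated correlation). With Socs3, these include Bcl2l1, which encodes the survival protein BCL-XL, (1.32, 87.1 ± 2.24 against 34.3 ± 0.488, 3.11e-06), Il6ra, the interleukin receptor that signals through STAT3, (1.22, 2.73 ± 0.0484 against 0.606 ± 0.00277, 8.10e-05) and Tnfrsf12a, the receptor of TWEAK, (0.995, 56.9 ± 0.517 against 28.1 ± 1.22, 1.02e-05). The STAT3 target counts became 8 to 9 rising and 2 falling after rescaling to a common sum or without water 1, water 2 or 3 h EGF 1. Among 19 immediate early genes tested, 11 rose, 5 fell and 3 did not pass (11 rose and 5 fell adjusted over the list alone, median log2 fold change 0.27). The immediate early list was called up by camera at adjusted p = 9.10e-04 (adjusted p = 0.227 with an estimated correlation). The largest were Ier3, an immediate early survival gene, (1.41, 6.03 ± 0.737 against 1.64 ± 0.234, 1.91e-04), Maff, a small MAF transcription factor, (1.06, 10.4 ± 0.386 against 4.50 ± 0.202, 5.65e-05) and Klf10, a TGF-beta-induced zinc finger factor, (0.64, 23.8 ± 0.707 against 14.8 ± 0.167, 2.41e-04), and Nr4a2, an orphan nuclear receptor, (−0.73, 10.8 ± 0.569 against 18.4 ± 0.624, 4.25e-04) fell. The immediate early counts of rising and falling members became 11 and 3 after rescaling to a common sum. The log2 fold change of Il6ra was 2.005 with pseudocount 0.1.

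Ligands and regulators of ERBB receptors rose more often than they fell. Of the 12 ERBB genes tested, 5 rose, 1 fell and 6 did not pass (5 rose and 1 fell adjusted over the list alone, median log2 fold change 0.18). The ERBB list was called up by camera at adjusted p = 2.03e-04 (adjusted p = 0.206 with an estimated correlation). Increases were Rhbdf2, an inactive rhomboid that controls release of EGFR ligands, (1.31, 6.35 ± 0.163 against 1.95 ± 0.0266, 3.66e-05), Hbegf, an EGFR ligand, (1.27, 16.8 ± 0.0112 against 6.37 ± 0.107, 3.94e-06) and Errfi1, a feedback inhibitor of EGFR, (0.60, 15.3 ± 0.911 against 9.78 ± 0.115, 3.26e-04), and Erbb3, a kinase-impaired ERBB receptor, (−0.55, 3.48 ± 0.0598 against 5.57 ± 0.0332, 3.80e-04) fell. Targets of FOXO factors fell where the largest changes lay. Among 17 PI3K-FOXO genes tested, 3 rose, 8 fell and 6 did not pass (5 rose and 8 fell adjusted over the list alone, median log2 fold change −0.04). The PI3K-FOXO list was not called by camera (adjusted p = 0.358). The falls were led by Fbxo32 (−1.16, 1.64 ± 0.0396 against 4.88 ± 0.145, 4.72e-05), Ccng2, a FOXO-induced cyclin of resting cells, (−0.78, 3.87 ± 0.257 against 7.36 ± 0.0896, 1.91e-04) and Arrdc3, an arrestin-domain protein, (−0.64, 10.2 ± 0.0942 against 16.4 ± 1.05, 0.00121), with Erbb3. The PI3K-FOXO counts of rising and falling members became 5 and 7 after median-ratio rescaling.

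Genes of cholesterol synthesis and some of ribosome assembly rose at 3 h. Of the 23 cholesterol genes tested, 15 rose, 2 fell and 6 did not pass (15 rose and 2 fell adjusted over the list alone, median log2 fold change 0.22). The cholesterol list was called up by camera at adjusted p = 9.04e-07 (adjusted p = 0.227 with an estimated correlation). They include Hsd17b7 (0.39, 22.7 ± 0.394 against 17.1 ± 0.9752, 0.00477) and Stard4, a cholesterol carrier, (0.35, 39.7 ± 1.03 against 30.9 ± 0.893, 0.00192). The cholesterol counts became 12 to 16 rising and 0 to 1 falling after median-ratio rescaling, after rescaling to a common sum, after quantile normalization or without Neo 1, Neo 2, water 1, water 2, 3 h EGF 1, 18 h EGF 1 or 18 h EGF 2. Among 30 ribosome biogenesis genes tested, 12 rose, 0 fell and 18 did not pass (12 rose and 0 fell adjusted over the list alone, median log2 fold change 0.11). The ribosome biogenesis list was called up by camera at adjusted p = 9.04e-07 (adjusted p = 0.227 with an estimated correlation). Rising members include Wdr43, a factor of small subunit assembly, (0.32, 43.5 ± 0.746 against 34.7 ± 0.304, 0.00123), Tsr1, a ribosome assembly factor, (0.25, 53.8 ± 0.351 against 45.2 ± 0.193, 0.00213), Ddx21, a nucleolar RNA helicase, (0.23, 79.7 ± 1.73 against 67.9 ± 0.921, 0.00293) and Noc4l, a ribosome assembly factor, (0.23, 24.5 ± 1.07 against 20.8 ± 1.33, 0.0464). The ribosome biogenesis counts of rising and falling members became 19 and 0 after median-ratio rescaling, 4 and 0 without water 1 and 5 and 0 without water 2. Genes of mitosis fell more often than they rose. Of the 29 G2/M genes tested, 2 rose, 16 fell and 11 did not pass (3 rose and 20 fell adjusted over the list alone, median log2 fold change −0.14). The G2/M list was called down by camera at adjusted p = 0.00308 (adjusted p = 0.554 with an estimated correlation). The largest falls were Nusap1, a spindle protein, (−0.31, 41.6 ± 0.636 against 51.9 ± 1.41, 0.00361), Cdca3, a trigger of mitotic entry, (−0.29, 62.2 ± 0.600 against 76.5 ± 1.83, 0.00407), Kif2c, a mitotic kinesin, (−0.26, 24.3 ± 0.381 against 29.4 ± 0.830, 0.00193) and Kif20a, a mitotic kinesin, (−0.25, 39.5 ± 0.824 against 47.3 ± 0.353, 0.00142). The G2/M counts became 0 to 2 rising and 2 to 21 falling after rescaling to a common sum or without water 1, water 2, 3 h EGF 1 or 3 h EGF 2. Noc4l lost its call without the FPKM filter, without the variance trend or without Neo 1, Neo 2, water 1, water 2, 3 h EGF 1 or 3 h EGF 2 (adjusted p = 0.0534 to 0.214). Kif2c and Kif20a did not keep the call after rescaling to a common sum (adjusted p = 0.0686 and 0.0748).

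Corticotrope genes changed in both directions at 3 h. Among 21 corticotrope genes tested, 1 rose, 5 fell and 15 did not pass (1 rose and 5 fell adjusted over the list alone, median log2 fold change −0.08). The corticotrope list was not called by camera (adjusted p = 0.358). Nr3c1, the glucocorticoid receptor, (−0.28, 34.7 ± 0.475 against 42.4 ± 0.225, 9.31e-04) and Scg5, a chaperone of prohormone convertase, (−0.16, 115 ± 1.08 against 128 ± 0.935, 0.00739) fell, and Sstr2, a somatostatin receptor, (0.22, 32.2 ± 1.48 against 27.6 ± 0.663, 0.00788) rose. The corticotrope counts became 0 to 2 rising and 1 to 3 falling after median-ratio rescaling, after rescaling to a common sum, after quantile normalization or without water 1, water 2, 18 h EGF 1 or 18 h EGF 2. Nr3c1 lost its call after rescaling to a common sum (adjusted p = 0.0577). Scg5 did not keep its call after rescaling to a common sum or without water 1 (adjusted p = 0.455 and 0.0604). Sstr2 had no call without water 1 (adjusted p = 0.0569).

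EGF for 18 h was compared with water in the EGFR line to ask what a long exposure changes, against water libraries labelled 3 h. Cdkn2b (2.95, 43.3 ± 1.78 against 4.71 ± 0.0793, 4.85e-08), Etv5 (2.72, 70.6 ± 1.49 against 9.86 ± 0.195, 4.85e-08) and Stc1 (2.69, 28.6 ± 1.28 against 3.60 ± 0.227, 9.66e-07) were the largest increases. They were joined by Kcnh1, a voltage-gated potassium channel, (2.36, 6.52 ± 0.0809 against 0.468 ± 0.0175, 1.37e-06) and Gprc5c (2.34, 37.3 ± 1.34 against 6.59 ± 0.583, 3.02e-06), and by Rab26, a small GTPase of secretory vesicles, (2.21, 12.7 ± 0.702 against 1.95 ± 0.312, 1.28e-05) and Lmo2, a LIM-only transcriptional cofactor, (2.07, 39.9 ± 0.205 against 8.74 ± 0.0448, 2.30e-07). Large decreases were Sln, the calcium pump inhibitor sarcolipin, (−1.29, 7.39 ± 3.54e-05 against 19.5 ± 0.983, 4.86e-05), Tex33 (−1.24, 2.18 ± 0.142 against 6.52 ± 0.0498, 3.41e-05), Dmpk, a serine/threonine kinase, (−1.14, 7.67 ± 0.905 against 18.1 ± 0.508, 3.81e-05) and Sgk1 (−1.12, 26.4 ± 2.17 against 58.4 ± 0.222, 2.03e-05). Next came Prr15l (−1.06, 11.3 ± 0.0237 against 24.8 ± 0.927, 4.73e-06), Sytl4, a granule-docking protein, (−1.02, 25.1 ± 0.911 against 52.0 ± 0.289, 1.13e-05), Gamt, an enzyme of creatine synthesis, (−1.02, 15.3 ± 0.412 against 31.9 ± 1.16, 5.31e-05) and Tat (−1.01, 5.399 ± 1.08 against 11.8 ± 1.08, 6.37e-04). Tbx19 (0.28, 109.9 ± 3.73 against 90.4 ± 2.82, 0.00482), Stat3 (0.13, 31.2 ± 0.159 against 28.3 ± 0.368, 0.0199) and Socs3 (0.74, 6.87 ± 0.380 against 3.70 ± 0.204, 1.28e-04) rose. Pomc (−0.12, 7628 ± 281 against 8274 ± 47.4, 0.206) and Egfr (0.21, 31.1 ± 1.11 against 26.7 ± 1.13, 0.0590) did not pass. The 95% interval of the Pomc log2 fold change ran from −0.27 to 0.04. Stat3 lost its call after rescaling to a common sum or without water 1, water 2, 18 h EGF 1 or 18 h EGF 2 (adjusted p = 0.0761 to 0.116). The log2 fold change of Kcnh1 was 3.54 with pseudocount 0.1. Egfr passed the test after median-ratio rescaling (adjusted p = 0.0365), with only the 2 groups fitted (adjusted p = 0.0227), without Neo 1 (adjusted p = 0.0218), without Neo 2 (adjusted p = 0.0215) and with protein-coding genes only, a choice made after seeing the data (adjusted p = 0.0269).

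At 18 h, of 10874 genes tested by limma-trend, 1437 were higher and 2030 lower at adjusted p below 0.05, of which 68 and 12 changed at least 2-fold. Higher genes were 41.4% of the calls, against 53.6% after median-ratio rescaling (1857 higher and 1610 lower) and 62.8% after rescaling to a common sum (1184 higher and 702 lower). Higher and lower counts became 868 and 927 without water 1, 873 and 1051 without water 2, 847 and 971 without 18 h EGF 1 and 926 and 1158 without 18 h EGF 2. Across the 19 lists with at least 5 genes tested, camera called 10 up and 3 down, fry 11 and 5, and camera with an estimated correlation 0 and 0, where 3 lists had an unadjusted p under 0.05.

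Genes of DNA replication and of mitosis fell at 18 h. Of the 28 S phase genes tested, 0 rose, 25 fell and 3 did not pass (0 rose and 27 fell adjusted over the list alone, median log2 fold change −0.26). The S phase list was called down by camera at adjusted p = 2.42e-10 (adjusted p = 0.205 with an estimated correlation). The largest falls were Ccne2, cyclin E2, (−0.41, 74.6 ± 1.61 against 99.7 ± 3.84, 3.17e-04), Slbp, the histone mRNA-binding protein, (−0.40, 67.3 ± 3.28 against 89.2 ± 0.0112, 3.66e-04), Rfc4, a subunit of the DNA clamp loader, (−0.39, 56.4 ± 0.663 against 74.3 ± 1.02, 3.53e-04) and Rrm1, a subunit of ribonucleotide reductase, (−0.39, 93.5 ± 1.53 against 123 ± 0.728, 8.64e-04). The S phase counts of rising and falling members became 0 and 16 after rescaling to a common sum. Among 29 G2/M genes tested, 0 rose, 23 fell and 6 did not pass (0 rose and 25 fell adjusted over the list alone, median log2 fold change −0.23). The G2/M list was called down by camera at adjusted p = 9.83e-09 (adjusted p = 0.205 with an estimated correlation). They include Bub1b, a spindle checkpoint kinase, (−0.41, 28.7 ± 0.407 against 38.5 ± 0.0185, 2.68e-04), Kif11, a mitotic kinesin, (−0.36, 43.7 ± 0.763 against 56.5 ± 1.18, 3.02e-04), Ccna2, cyclin A2, (−0.35, 67.5 ± 1.26 against 86.2 ± 0.705, 3.96e-04) and Nusap1 (−0.34, 40.9 ± 1.13 against 51.9 ± 1.41, 0.00183). The G2/M counts of rising and falling members became 0 and 12 after rescaling to a common sum.

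At 18 h too, ERK output and STAT3 target genes rose more often than they fell. Of the 12 ERK genes tested, 9 rose, 1 fell and 2 did not pass (9 rose and 1 fell adjusted over the list alone, median log2 fold change 0.54). The ERK list was called up by camera at adjusted p = 4.46e-07 (adjusted p = 0.170 with an estimated correlation). They include Etv5 (2.72, 70.6 ± 1.49 against 9.86 ± 0.195, 4.85e-08), Dusp5 (1.77, 99.4 ± 0.194 against 28.5 ± 0.721, 1.37e-06), Plaur (1.59, 5.89 ± 0.238 against 1.298 ± 0.228, 3.00e-05) and Spred2, an inhibitor of RAS-ERK signalling, (0.85, 6.14 ± 0.252 against 2.97 ± 0.129, 2.96e-04). Among 18 STAT3 target genes tested, 8 rose, 2 fell and 8 did not pass (10 rose and 4 fell adjusted over the list alone, median log2 fold change 0.13). The STAT3 target list was called up by camera at adjusted p = 0.00113 (adjusted p = 0.205 with an estimated correlation). The largest were Il6ra (1.29, 2.94 ± 0.0830 against 0.606 ± 0.00277, 3.21e-05), Bcl2l1 (1.23, 81.8 ± 2.11 against 34.3 ± 0.488, 2.15e-06) and Tnfrsf12a (0.65, 44.6 ± 0.819 against 28.1 ± 1.22, 3.66e-05), with Socs3. The log2 fold change of Il6ra was 2.10 with pseudocount 0.1.

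Interferon-induced genes rose at 18 h, from low levels. Of the 9 interferon genes tested, 8 rose, 0 fell and 1 did not pass (8 rose and 0 fell adjusted over the list alone, median log2 fold change 0.60). The interferon list was called up by camera at adjusted p = 6.64e-06 (adjusted p = 0.223 with an estimated correlation). They include Usp18, an interferon-induced isopeptidase, (1.46, 8.54 ± 2.95 against 2.38 ± 0.00755, 0.00104), Isg15, an interferon-induced ubiquitin-like modifier, (1.15, 10.2 ± 2.70 against 4.001 ± 0.709, 0.00224), Bst2, the antiviral protein tetherin, (0.89, 19.998 ± 6.81 against 10.05 ± 0.224, 0.0107) and Oas1a, an antiviral oligoadenylate synthetase, (0.87, 7.79 ± 2.83 against 3.68 ± 0.148, 0.0112). The 2 libraries of 18 h EGF were unequal, at FPKM of Usp18 6.46 and 10.6, Isg15 8.31 and 12.1, Bst2 15.2 and 24.8 and Oas1a 5.79 and 9.79 in 18 h EGF 1 and 2. Unfolded protein and stress response genes rose more often than they fell. Among 26 unfolded protein genes tested, 15 rose, 3 fell and 8 did not pass (15 rose and 5 fell adjusted over the list alone, median log2 fold change 0.14). The unfolded protein list was called up by camera at adjusted p = 8.61e-04 (adjusted p = 0.401 with an estimated correlation). The largest were Pdia6, a protein disulfide isomerase, (0.69, 411 ± 6.71 against 255 ± 1.23, 2.49e-05), Pdia4, a protein disulfide isomerase, (0.36, 188 ± 4.15 against 146 ± 0.870, 7.52e-04), Hyou1, a chaperone of the endoplasmic reticulum, (0.35, 138 ± 2.89 against 108 ± 1.11, 3.57e-04) and Hsp90b1, a chaperone of the endoplasmic reticulum, (0.34, 694 ± 8.41 against 548 ± 3.60, 4.86e-04). The unfolded protein counts of rising and falling members became 10 and 1 after rescaling to a common sum and 9 and 3 without 18 h EGF 1. Bst2 lost its call without water 2 (adjusted p = 0.0523). Oas1a did not keep its call without water 1 (adjusted p = 0.0583). The log2 fold change of Bst2 was 0.55 without 18 h EGF 2. The log2 fold change of Oas1a was 0.54 without 18 h EGF 2.

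Corticotrope genes moved both ways at 18 h. Of the 21 corticotrope genes tested, 7 rose, 6 fell and 8 did not pass (8 rose and 6 fell adjusted over the list alone, median log2 fold change 0.05). The corticotrope list was not called by camera (adjusted p = 0.382). Scg2, the granin secretogranin II, (1.11, 264 ± 1.06 against 121 ± 2.83, 4.73e-06) and Chgb, a granin of secretory granules, (0.58, 1379 ± 17.0 against 923 ± 0.240, 1.98e-04) rose with Tbx19, and Sstr5 (−0.54, 9.61 ± 0.135 against 14.4 ± 0.114, 4.76e-05) fell. The corticotrope counts became 4 rising and 4 to 6 falling after rescaling to a common sum or without water 1, water 2, 18 h EGF 1 or 18 h EGF 2.

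**Figure D3:**
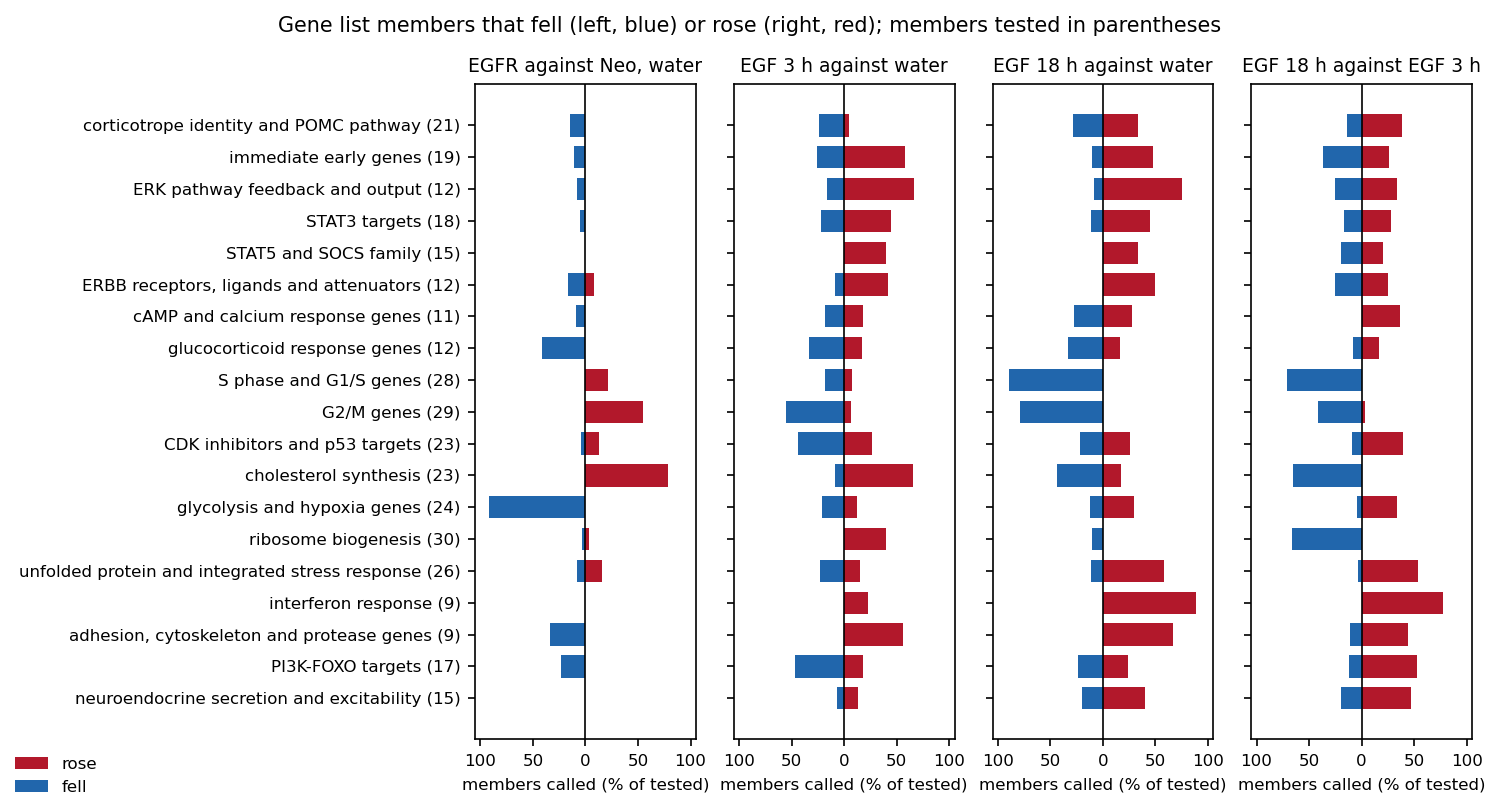
Percent of tested members called lower (left, blue) and higher (right, red) for each of 19 gene lists in the 4 comparisons, n = 2 libraries per group. S phase and G1/S genes have 25 of 28 members lower at 18 h of EGF, against 5 at 3 h.

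EGF for 18 h was compared with EGF for 3 h to ask which responses differ with time, with culture time changing alongside. Higher at 18 h were Grb14, an adapter that inhibits receptor tyrosine kinases, (1.68, 32.5 ± 0.729 against 9.44 ± 0.198, 4.02e-06) and Rab26 (1.48, 12.7 ± 0.702 against 3.90 ± 0.102, 1.73e-04). So were Usp18 (1.43, 8.54 ± 2.95 against 2.47 ± 0.167, 0.00178) and Rit2, a RAS-like GTPase, (1.38, 29.2 ± 6.36e-04 against 10.6 ± 0.02001, 1.27e-05). Lower at 18 h were Nab2, a corepressor of EGR factors, (−1.36, 6.01 ± 0.243 against 17.0 ± 0.996, 2.81e-05), Dmpk (−0.95, 7.67 ± 0.905 against 15.6 ± 0.171, 2.03e-04), Sln (−0.88, 7.39 ± 3.54e-05 against 14.5 ± 1.85, 5.51e-04), Cib3, a calcium and integrin binding protein, (−0.88, 2.63 ± 0.271 against 5.68 ± 0.377, 4.58e-04) and Myh14, a nonmuscle myosin heavy chain, (−0.83, 7.96 ± 0.0403 against 14.9 ± 0.129, 1.87e-04). Tbx19 was higher (0.38, 109.9 ± 3.73 against 84.4 ± 0.823, 0.00194). Pomc (0.08, 7628 ± 281 against 7206 ± 318, 0.364), Stat3 (−0.09, 31.2 ± 0.159 against 33.2 ± 1.05, 0.0848), Socs3 (0.08, 6.87 ± 0.380 against 6.41 ± 0.0993, 0.281) and Egfr (0.07, 31.1 ± 1.11 against 29.7 ± 1.29, 0.505) did not pass. The 95% interval of the Pomc difference ran from −0.07 to 0.24. Stat3 passed the test after median-ratio rescaling (adjusted p = 0.0357) and after quantile normalization (adjusted p = 0.0277).

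Between the EGF times, of 10874 genes tested by limma-trend, 1922 were higher and 1741 lower at adjusted p below 0.05, of which 20 and 4 changed at least 2-fold. Higher genes were 52.5% of the calls, against 39.4% after rescaling to a common sum (863 higher and 1326 lower) and 48.3% after quantile normalization (1879 higher and 2013 lower). Higher and lower counts became 1130 and 1227 without 3 h EGF 1, 1060 and 817 without 18 h EGF 1 and 1056 and 916 without 18 h EGF 2. Across the 19 lists with at least 5 genes tested, camera called 5 up and 4 down, fry 8 and 4, and camera with an estimated correlation 0 and 0, where 1 list had an unadjusted p under 0.05.

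Cholesterol synthesis and ribosome assembly genes were lower at 18 h than at 3 h. Among 23 cholesterol genes tested, 0 were higher, 15 were lower and 8 did not pass (0 were higher and 16 were lower adjusted over the list alone, median log2 fold change −0.29). The cholesterol list was called down by camera at adjusted p = 9.14e-08 (adjusted p = 0.375 with an estimated correlation). The largest were Idi1, isopentenyl diphosphate isomerase, (−0.67, 65.1 ± 0.852 against 104 ± 3.54, 2.95e-04), Hsd17b7 (−0.66, 14.0 ± 0.674 against 22.7 ± 0.394, 6.93e-04), Hmgcs1, HMG-CoA synthase, (−0.49, 105.1 ± 0.756 against 148 ± 5.95, 7.53e-04) and Msmo1, a sterol oxidase, (−0.46, 136 ± 3.83 against 187 ± 4.84, 5.99e-04). Of the 30 ribosome biogenesis genes tested, 0 were higher, 20 were lower and 10 did not pass (0 were higher and 22 were lower adjusted over the list alone, median log2 fold change −0.18). The ribosome biogenesis list was called down by camera at adjusted p = 2.08e-09 (adjusted p = 0.375 with an estimated correlation). They include Wdr43 (−0.37, 33.5 ± 0.838 against 43.5 ± 0.746, 7.11e-04), Noc4l (−0.34, 19.2 ± 1.68 against 24.5 ± 1.07, 0.0107), Polr1b, a subunit of RNA polymerase I, (−0.30, 19.1 ± 0.517 against 23.8 ± 0.559, 0.00140) and Dkc1, the pseudouridine synthase dyskerin, (−0.30, 21.8 ± 0.272 against 27.2 ± 0.821, 0.00467). The ribosome biogenesis counts of higher and lower members became 0 and 12 without 18 h EGF 1 and 0 and 11 without 18 h EGF 2. Noc4l lost its call without 3 h EGF 2 or 18 h EGF 2 (adjusted p = 0.0516 and 0.0544).

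Among unfolded protein genes and FOXO targets, more were higher than lower at 18 h against 3 h. Among 26 unfolded protein genes tested, 14 were higher, 1 was lower and 11 did not pass (15 were higher and 1 was lower adjusted over the list alone, median log2 fold change 0.12). The unfolded protein list was called up by camera at adjusted p = 0.00274 (adjusted p = 0.484 with an estimated correlation). They include Pdia6 (0.68, 411 ± 6.71 against 257 ± 7.11, 1.03e-04), Atf3, a stress-induced transcription factor, (0.37, 13.8 ± 0.710 against 10.4 ± 0.783, 0.00387), Pdia4 (0.35, 188 ± 4.15 against 147 ± 7.61, 0.00135) and Hsp90b1 (0.35, 694 ± 8.41 against 545 ± 11.6, 8.29e-04). The unfolded protein counts of higher and lower members became 7 and 1 after rescaling to a common sum and 9 and 0 without 18 h EGF 2. Of the 17 PI3K-FOXO genes tested, 9 were higher, 2 were lower and 6 did not pass (9 were higher and 2 were lower adjusted over the list alone, median log2 fold change 0.27). The PI3K-FOXO list was called up by camera at adjusted p = 0.0224 (adjusted p = 0.375 with an estimated correlation). The largest were Fbxo32 (0.63, 3.09 ± 0.179 against 1.64 ± 0.0396, 5.65e-04), Erbb3 (0.45, 5.10 ± 0.180 against 3.48 ± 0.0598, 9.04e-04), Foxo3, a forkhead transcription factor restrained by AKT, (0.43, 15.7 ± 0.278 against 11.4 ± 0.276, 5.60e-04) and Sesn1, a stress-induced inhibitor of mTORC1, (0.42, 11.2 ± 0.245 against 8.10 ± 0.0265, 6.93e-04). Camera's call of the PI3K-FOXO list ended without 3 h EGF 2 (adjusted p = 0.160).

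Corticotrope genes differed in both directions between the EGF times. Among 21 corticotrope genes tested, 8 were higher, 3 were lower and 10 did not pass (8 were higher and 3 were lower adjusted over the list alone, median log2 fold change 0.08). The corticotrope list was not called by camera (adjusted p = 0.185). Scg2 (1.07, 264 ± 1.06 against 125 ± 5.98, 1.66e-05) and Chgb (0.56, 1379 ± 17.0 against 937 ± 45.8, 4.94e-04) were higher with Tbx19, and Sstr5 was lower (−0.48, 9.61 ± 0.135 against 13.8 ± 0.159, 1.88e-04). The corticotrope counts of higher and lower members became 5 and 3 after rescaling to a common sum and 5 and 2 without 18 h EGF 2.

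The 3 h and 18 h calls were joined to ask how responses to EGF follow over time. Transient genes, called at 3 h and called the other way between 18 h and 3 h, were 491 that rose and 735 that fell. Sustained genes, called the same way at both times with no call between them, were 368 and 640. Late genes, called at 18 h and further in that direction than at 3 h, were 711 and 815. Wdr43, Tsr1 and Hbegf were transient, Bcl2l1, Dusp5 and Socs3 sustained, and Ccne2, Pdia6 and Cdkn2b late. A transient response need not have ended by 18 h, and a late one can be present at 3 h. In log2, Hbegf was 1.27 above water at 3 h and 0.66 at 18 h, and Cdkn2b 2.21 and 2.95. A further 58 genes rose at 3 h and were below water at 18 h (first higher), and 85 fell at 3 h and were above water at 18 h (first lower). The 3 h and 18 h EGF responses shared 613 genes higher and 911 lower. Independent lists would share 169.5 and 399.9, and unchanged groups simulated against the same water libraries 0.010 and 0.0300. With no effect hardly any gene is called, so the simulated counts lie near 0 and do not measure the overlap that shared controls add to real effects. Fold changes at the 2 times correlated at r = 0.580 across genes (simulated 0.492), with covariance 0.0501 (simulated 0.0118), and 0.0283 (0.00231) without small RNA genes. Both responses use the same 2 water libraries, too few to give each response 2 of its own, so part of the excess may come from the shared controls.

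These class and overlap counts depended on single libraries and on scaling. Without water 1 there were 266 transient higher, 365 transient lower, 201 sustained higher, 184 sustained lower, 482 late lower, 9 first higher, 9 first lower, 335 shared higher and 274 shared lower genes. Without water 2 there were 225 transient higher, 377 transient lower, 195 sustained higher, 205 sustained lower, 524 late lower, 9 first higher, 9 first lower, 326 shared higher and 297 shared lower genes. Without 3 h EGF 1 there were 229 transient higher, 300 transient lower, 383 sustained lower, 35 first higher, 33 first lower and 513 shared lower genes. Without 18 h EGF 1 there were 290 transient higher, 408 transient lower, 373 sustained lower, 423 late higher, 345 late lower, 17 first higher, 30 first lower and 473 shared lower genes. Without 18 h EGF 2 there were 287 transient higher, 400 transient lower, 407 sustained lower, 446 late higher, 414 late lower, 22 first higher, 22 first lower and 518 shared lower genes. After rescaling to a common sum there were 166 transient lower, 106 sustained lower, 467 late higher, 371 late lower, 11 first higher, 9 first lower and 134 shared lower genes. With only the 2 groups fitted there were 458 transient lower and 56 first lower genes. After median-ratio rescaling there were 389 sustained lower genes.

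**Figure D4:**
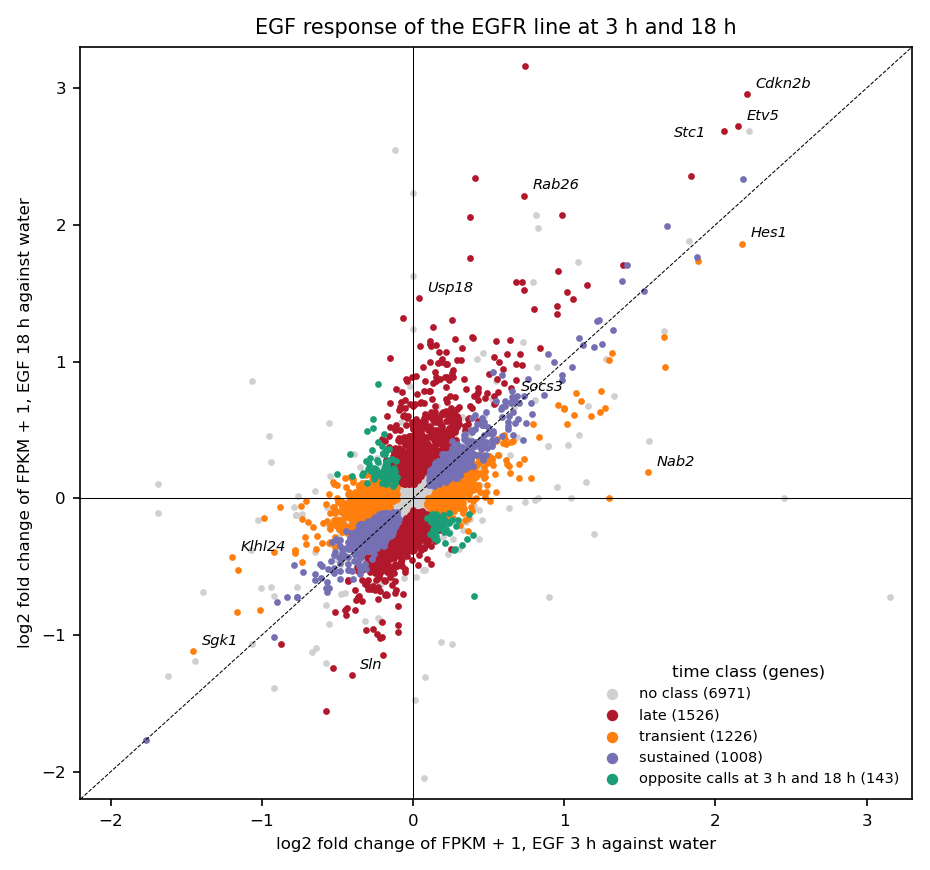
Log2 fold change at 18 h (y) against 3 h (x) of EGF, each against water in the EGFR line, one point per gene (10874 genes, 22 outside the axes), coloured by time class. 1526 genes are late, 1226 transient, 1008 sustained and 143 opposite at the 2 times.

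The EGFR against Neo difference was set beside the EGF responses to ask whether the unstimulated receptor line and the ligand move the same genes. Glycolysis and hypoxia genes, 22 of 24 lower in the EGFR line, had 3 that rose and 5 that fell after 3 h of EGF, and 7 and 3 after 18 h. Cholesterol genes, 18 of 23 higher in the line, had 15 that rose and 2 that fell at 3 h, and 4 and 10 at 18 h. G2/M genes, 16 of 29 higher in the line, had 2 that rose and 16 that fell at 3 h, and 0 and 23 at 18 h. Across genes the line difference and the 3 h response correlated at r = −0.364 (simulated −0.491, because water enters with opposite signs). With the 18 h response it was −0.2999 (simulated −0.513). Covariance was −0.0250 at 3 h (simulated −0.0119) and −0.0209 at 18 h (simulated −0.0124). Without small RNA genes it was −0.00622 (−0.00231) and −0.00804 (−0.00236), and the 3 h r was −0.217. Genes higher in the line and lower after 3 h of EGF numbered 146 (independent lists 66.6, simulated 0), and genes higher in both 27 (39.9 and 0). Part of the excess may come from the shared water libraries. The 3 h correlation became −0.507 without water 1, −0.543 without water 2 and −0.171 with protein-coding genes only, the last chosen after seeing the data. The 18 h correlation became −0.183 without Neo 1, −0.463 without water 1 and −0.484 without water 2.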

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

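The test of reads shared with copies, the test of receptor activity and the Pomc test were chosen only after the result was seen. A result was picked out here where the EGF effect at 18 h differed from that at 3 h by the test of the 18 h against 3 h difference, which held for 119 of 157 genes named for EGF and 9 lists (adjusted p below 0.05). Some of these genes were named because they differed in this comparison, so their share is fixed in part by that choice, and of all 10874 genes 1922 were higher and 1741 lower. For 67 of the named genes the effect was higher at 18 h. The difference, in log2, was Grb14 1.68, Rab26 1.48, Usp18 1.43, Rit2 1.38, Lmo2 1.09, Scg2 1.07, Isg15 1.04, Oas1a 0.92, Bst2 0.89, Hbp1 0.84, Fbxl20 0.82, Klhl24 0.76, Cdkn2b 0.74, Vgf 0.70, Pdia6 0.68, Stc1 0.63 and Fbxo32 0.63. Smaller differences were Etv5 0.57, Chgb 0.56, Aldoc 0.53, Foxn3 0.53, Kcnh1 0.52, Pde4b 0.52, Syt4 0.50, Bbc3 0.48, Shc1 0.47, Anxa2 0.45, Erbb3 0.45, Nfkb1 0.43, Trp53inp1 0.43, Foxo3 0.43, Sesn1 0.42, Maff 0.40 and Ccng2 0.40. Next came Tbx19 0.38, Pde4d 0.38, Atf3 0.37, Pdia4 0.35, Hsp90b1 0.35, Tgm2 0.35, Sgk1 0.34, Amotl2 0.33, Dusp8 0.32, Plk2 0.32, Il4ra 0.31, Rab3a 0.31, Unc13a 0.29, Hyou1 0.28, Irs2 0.28, Pim1 0.27 and Txnip 0.27. The smallest were Arrdc3 0.27, Lrig1 0.27, Mt1 0.26, Spred2 0.25, Stat2 0.24, Itga3 0.24, Pfkl 0.22, Pdk1 0.22, Eno2 0.22, Tyk2 0.20, Mycl 0.19, Itgb1 0.19, Sik1 0.16, Cdh2 0.13, Chac1 0.12 and Kif2c 0.11. For 52 of them it was lower at 18 h. Near 0 on the lower side were Ero1l −0.11, Cdc45 −0.15, Enc1 −0.15, Bub1b −0.18, Prr15l −0.19, Errfi1 −0.19, Kif11 −0.20, Klf10 −0.23, Sox2 −0.23, Tsr1 −0.23, Socs4 −0.23, Ccna2 −0.25, Rhbdf2 −0.25, Bub1 −0.25, Ptpn2 −0.26, Rrm1 −0.26 and Trib1 −0.26. Larger decreases were Ddx21 −0.27, Dusp4 −0.27, Kif23 −0.28, Rfc4 −0.28, Gata2 −0.28, Fdft1 −0.29, Top2a −0.29, Dkc1 −0.30, Polr1b −0.30, Hes1 −0.32, Slbp −0.32, Klf4 −0.33, Spred1 −0.33, Noc4l −0.34, Tnfrsf12a −0.34, Cdc6 −0.35 and Gadd45b −0.37. Then came Wdr43 −0.37, Rrm2 −0.40, Ccne2 −0.45, Msmo1 −0.46, Sstr5 −0.48, Hmgcs1 −0.49, Hbegf −0.61, Hsd17b7 −0.66, Idi1 −0.67, Sh2d5 −0.71, Tex33 −0.71, Sytl4 −0.80, Gamt −0.81, Myh14 −0.83, Cib3 −0.88, Sln −0.88 and Dmpk −0.95. The largest decreases were Nab2 −1.36. The lists were picked out by camera, with medians of −0.195 (S phase and G1/S genes), −0.0945 (G2/M genes), 0.0717 (CDK inhibitors and p53 targets), −0.286 (cholesterol synthesis), 0.0957 (glycolysis and hypoxia genes), −0.177 (ribosome biogenesis), 0.120 (unfolded protein and integrated stress response), 0.487 (interferon response) and 0.270 (PI3K-FOXO targets), all with adjusted p of at least 0.375 with an estimated correlation. The call of the CDK inhibitor and p53 list ended after median-ratio rescaling, after rescaling to a common sum or without Neo 1, Neo 2, water 1, water 2 or 3 h EGF 2 (adjusted p = 0.0509 to 0.0989), that of the glycolysis and hypoxia list ended without 18 h EGF 1 (adjusted p = 0.193), and that of the PI3K-FOXO list ended without 3 h EGF 2 (adjusted p = 0.160).

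In water, 22 of 24 glycolysis and hypoxia genes were lower in the EGFR line than in Neo. The authors' normalization is argued against, since at least 19 were lower under each of 3 rescalings, and so are reads shared with paralogs or pseudogenes, since 14 of 16 members without a near-identical copy were lower (median −0.65). Receptor activity in the EGFR line stays open: the list's median after 3 h of EGF was −0.0694 and camera did not call it (adjusted p = 0.734), while at 18 h camera called it up (adjusted p = 0.0208, and 0.506 with an estimated correlation, median 0.0730, 7 rose and 3 fell), a call that ended without water 1 or 18 h EGF 1 (adjusted p = 0.0564 and 0.191). As a hypothesis, the EGFR cultures may have been less hypoxic or less dense, which oxygen and density measured in several clones of each line would test.

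Pomc was not higher after EGF, at a log2 fold change of −0.20 after 3 h and −0.12 after 18 h (95% interval at 18 h −0.27 to 0.04). At 3 h the authors' normalization stays open only for a rise to 0.0643, the highest 95% upper end under 2 rescalings. Quantile normalization decides nothing here, since it gives Pomc the value of its rank and its log2 fold change is then 0 (−0.183 to 0.183). A hypothesis is that EGF could act on nascent Pomc transcription before the large mRNA pool changes, which nascent RNA at minutes to hours would test.

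Interferon-induced genes rose at 18 h in 8 of the 9 members tested, of 28 listed. A single deviating library is argued against (at least 7 members rose without 1 or the other 18 h library), as is the authors' normalization (at least 8 under each rescaling). Time in culture stays open, with 0 water libraries of 18 h. As a hypothesis, EGF may raise interferon signalling late, which water controls at 18 h and a JAK inhibitor would test.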

How the results depend on the processing

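The alternatives were fixed before the data were examined, apart from the restriction to protein-coding genes, which was chosen only after the result was seen. Median-ratio rescaling gave sustained lower 389. Rescaling to a common sum gave EGFR against Neo lower 103, EGF 3 h lower 441, EGF 18 h lower 702, 18 h against 3 h higher 863, transient lower 166, sustained lower 106, late higher 467, late lower 371, first higher 11, first lower 9 and shared lower 134. Fitting only the 2 groups gave EGFR against Neo higher 108 and lower 129, transient lower 458 and first lower 56. A replicate block gave EGFR against Neo higher 183 and lower 199. At an absolute log2 fold change of at least 1, higher and lower counts were 4 and 18 for EGFR against Neo. EGF 3 h had 44 and 10, EGF 18 h had 68 and 12, and 18 h against 3 h had 20 and 4. Transient counts were 2 and 1, sustained 27 and 2, late 14 and 0, first 0 and 0 and shared 27 and 2. At adjusted p below 0.01 higher and lower counts were 33 and 80 for EGFR against Neo. EGF 3 h had 604 and 773 and EGF 18 h had 820 and 919. For 18 h against 3 h these were 920 and 746, with 2 lists up. Transient counts were 165 and 242, sustained 217 and 197, late 397 and 333, first 10 and 13 and shared 305 and 256. With an estimated correlation every count of lists called up or down was 0. With fry there were EGF 3 h lists down 4, EGF 18 h lists down 5 and 18 h against 3 h lists up 8. Protein-coding genes only, added after seeing the data, gave EGFR against Neo higher 530 and line and 3 h correlation −0.171. With all libraries, camera called 4 lists up and 7 down for EGFR against Neo and 8 and 1 at 3 h. It called 10 and 3 at 18 h, and 4 down for 18 h against 3 h. Leaving out each library in turn gave EGFR against Neo higher 22 to 381 (all libraries 338), EGFR against Neo lower 63 to 308 (all libraries 315), EGF 3 h higher 616 to 1297 (all libraries 1283), EGF 3 h lower 808 to 2299 (all libraries 2142), EGF 18 h higher 847 to 1439 (all libraries 1437), EGF 18 h lower 927 to 2171 (all libraries 2030), 18 h against 3 h higher 1056 to 1896 (all libraries 1922) and 18 h against 3 h lower 817 to 1749 (all libraries 1741). The time classes and overlaps ran as transient higher 225 to 489 (all libraries 491), transient lower 300 to 855 (all libraries 735), sustained higher 195 to 359 (all libraries 368), sustained lower 184 to 742 (all libraries 640), late higher 423 to 731 (all libraries 711), late lower 345 to 825 (all libraries 815), first higher 9 to 60 (all libraries 58), first lower 9 to 97 (all libraries 85), shared higher 326 to 602 (all libraries 613) and shared lower 274 to 968 (all libraries 911). The others ran as line and 3 h correlation −0.543 to −0.292 (all libraries −0.364), line and 18 h correlation −0.484 to −0.183 (all libraries −0.2999) and 18 h against 3 h lists up 3 to 6 (all libraries 5). A group with 1 library left is assumed to vary like the others. Stricter thresholds lower counts by construction, and the cause of the other shifts was not tested. There was no sign that the replicate numbers pair the libraries: same-numbered deviations correlated at −0.172 to 0.310, and at −0.366 to 0.103 without small RNA genes. The block moved no other count by over 1.5 times, and under it 13 calls of named genes and the calls of 2 lists ended and 1 gene gained a call. Of 3008 values of named genes under other settings, 2888 gave the same outcome (a call in the same direction, or no call in either fit), 111 lost a call, 9 gained one and 0 turned direction, and with a library left out 2434, 250, 4 and 0 of 2688. The scaling of FPKM limits the split of small changes into higher and lower.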

Other observations

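The gene lists and tests here were fixed before the data were examined, while the genes called in opposite directions were chosen after the result was seen. Adhesion and protease genes that changed rose after 3 h of EGF. Of the 9 adhesion genes tested, 5 rose, 0 fell and 4 did not pass (5 rose and 0 fell adjusted over the list alone, median log2 fold change 0.23). The adhesion list was called up by camera at adjusted p = 1.36e-05 (adjusted p = 0.150 with an estimated correlation). With Plaur, Plat, tissue plasminogen activator, (0.99, 10.9 ± 0.338 against 4.99 ± 0.192, 5.08e-05) and Anxa2, a calcium-dependent membrane-binding protein, (0.35, 88.2 ± 4.18 against 68.9 ± 0.765, 0.00232) rose. CDK inhibitors and p53 targets split at 3 h. Among 23 CDK inhibitor and p53 genes tested, 6 rose, 10 fell and 7 did not pass (6 rose and 11 fell adjusted over the list alone, median log2 fold change −0.10, mean 0.07). The CDK inhibitor and p53 list, ranked down by camera, was not called (adjusted p = 0.904). Cdkn2b, Plk2, a polo-like kinase, (1.39, 47.2 ± 1.43 against 17.4 ± 0.0250, 1.34e-06) and Cdkn2a, the INK4A/ARF locus, (0.46, 3.71 ± 0.0169 against 2.44 ± 0.299, 0.0151) rose and Trp53inp1, a stress gene induced by p53, (−0.71, 11.7 ± 0.749 against 19.8 ± 0.960, 7.45e-04) fell. The CDK inhibitor and p53 counts of rising and falling members became 6 and 4 after rescaling to a common sum, 3 and 6 without water 1 and 4 and 6 without 3 h EGF 1. Cdkn2a lost its call without water 1 or 3 h EGF 1 (adjusted p = 0.0829 and 0.0719). Of the 15 STAT5 and SOCS genes tested, 6 rose, 0 fell and 9 did not pass (6 rose and 1 fell adjusted over the list alone, median log2 fold change 0.03). The STAT5 and SOCS list was called up by camera at adjusted p = 0.0364 (adjusted p = 0.286 with an estimated correlation). Rising members include Socs5, a suppressor of cytokine signalling, (0.47, 7.86 ± 0.209 against 5.41 ± 0.252, 0.00188). The STAT5 and SOCS counts of rising and falling members became 3 and 0 without water 2. Camera's call of the STAT5 and SOCS list ended after median-ratio rescaling (adjusted p = 0.0525), after rescaling to a common sum (adjusted p = 0.0781), without water 2 (adjusted p = 0.0544) and without 3 h EGF 1 (adjusted p = 0.0693).

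Secretory and cAMP-responsive genes rose or fell singly at 18 h. Among 15 neuroendocrine genes tested, 6 rose, 3 fell and 6 did not pass (8 rose and 4 fell adjusted over the list alone, median log2 fold change 0.14). The neuroendocrine list was called up by camera at adjusted p = 0.0498 (adjusted p = 0.205 with an estimated correlation). With Scg2 and Chgb, Syt4, a synaptotagmin of secretory vesicles, (1.03, 96.9 ± 0.468 against 46.8 ± 0.137, 3.86e-05) and Unc13a, a vesicle priming factor, (0.47, 37.8 ± 0.922 against 27.0 ± 0.431, 1.59e-04) rose. Camera's call of the neuroendocrine list ended after median-ratio rescaling (adjusted p = 0.0678), after quantile normalization (adjusted p = 0.0538), without Neo 1 (adjusted p = 0.0634), without Neo 2 (adjusted p = 0.0632), without water 1 (adjusted p = 0.0634) and without 18 h EGF 1 (adjusted p = 0.0578). Of the 11 cAMP and calcium genes tested, 3 rose, 3 fell and 5 did not pass (5 rose and 3 fell adjusted over the list alone, median log2 fold change 0.07). The cAMP and calcium list was not called by camera (adjusted p = 0.201). Vgf, a neuroendocrine secretory protein, (1.66, 93.7 ± 1.87 against 29.0 ± 0.547, 2.15e-06) and Rgs2, an inhibitor of G protein signalling, (0.90, 9.84 ± 1.52 against 4.79 ± 0.460, 0.00130) rose. Among 12 glucocorticoid genes tested, 2 rose, 4 fell and 6 did not pass (2 rose and 4 fell adjusted over the list alone, median log2 fold change −4.32e-04). The glucocorticoid list was not called by camera (adjusted p = 0.766). Sgk1 and Tat fell, and Cdkn1a (0.30, 18.5 ± 0.0142 against 14.9 ± 0.189, 8.64e-04) rose. The glucocorticoid counts of rising and falling members became 2 and 2 after rescaling to a common sum. Of 3 NF-kB genes tested, 1 rose at 18 h, Nfkb1, a subunit of NF-kB, (0.45, 32.1 ± 0.242 against 23.2 ± 0.544, 2.15e-04), and of 2 genes of other pituitary lineages 2 were lower at 18 h than at 3 h, Gata2, a transcription factor of gonadotropes and thyrotropes, (−0.28, 9.23 ± 0.292 against 11.4 ± 0.794, 0.0140) and Sox2, a transcription factor of pituitary stem cells, (−0.23, 3.54 ± 0.0639 against 4.33 ± 0.330, 0.0359), too few for a list test. Gata2 lost its call without 3 h EGF 1 or 18 h EGF 1 (adjusted p = 0.0747 and 0.0767). Sox2 did not keep its call after rescaling to a common sum, with only the 2 groups fitted or without water 1, water 2, 3 h EGF 1, 18 h EGF 1 or 18 h EGF 2 (adjusted p = 0.0557 to 0.166).

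Of the genes called one way at 3 h and the other way at 18 h, levels in water, at 3 h and at 18 h were Wbscr27 (5.99 ± 0.0997, 4.94 ± 0.0628 and 11.5 ± 0.302), Fam117a (19.7 ± 0.310, 16.2 ± 0.311 and 30.004 ± 1.85), Pdcd4 (22.1 ± 0.0875, 18.7 ± 0.934 and 29.8 ± 0.817), Idi1 (83.0 ± 0.594, 104 ± 3.54 and 65.1 ± 0.852), Cry1 (8.68 ± 0.313, 11.4 ± 0.189 and 6.89 ± 0.157) and Hells (43.6 ± 0.700, 52.8 ± 1.32 and 33.3 ± 0.121). Idi1, the clock repressor Cry1 and the chromatin remodeller Hells rose first and the translation inhibitor Pdcd4 fell first.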
